A study of Mus musculus with 4 samples.

How the data were processed

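Binding of the glucocorticoid receptor (GR), the nuclear receptor activated by corticosterone, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in 33AP1C9 cells. Per the labels, this mouse mammary line descends from C127 cells and carries a hormone-responsive viral promoter reporter. The cells were left untreated or received 600 nM corticosterone for 1 h or 12 h. The labels list 4 samples, of which 3 have a peak list (untreated, 1 h and 12 h, with 1 library per condition). The fourth is a genomic input sample, and a list for it was not used here. A further limit is that its label gives a corticosterone treatment, while the header of the untreated list names an untreated input as control, so the treatment of the input was left open.

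Reads were handled with bcl2fastq 2.17, Bowtie2 2.2.6 and HOMER, on mm10, per the submitters' processing notes; the HOMER version is not given in the sources used here. Peaks were called per library with HOMER findPeaks in its factor style, per the file headers, at a false discovery rate of 0.001, with a tag threshold of 75 in each treated library, a fold of at least 6 over the control and over the surrounding 10 kb, and a Poisson p-value of at most 0.0001. Per the file headers, both treated lists were called against the untreated ChIP library, whereas the untreated list was called against the input. A listed site in a treated library therefore stood above the untreated library by construction. Peaks had a fixed width within a list, which was 142 bp in the untreated, 282 bp in the 1 h and 302 bp in the 12 h list.

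The signal used throughout is the deposited normalised tag count, which HOMER gave scaled to a library of 10000000 tags, per the file headers, called normalised tags below. The deposited score per peak is the authors' own value from the caller and, in the values reported, served only to rank, describe or filter peaks within 1 list. The fold over control and the fold over the local region are ratios computed by the caller and deposited by the authors. The tag count of the untreated peak was deposited as a whole number. The deposited tag counts of the treated lists had been scaled by the authors to the size of the untreated library; scaling them back gave whole tags for 100% of peaks, within 0.1 of a tag. The deposited p-value per peak, which the caller printed as 0 below its smallest number, was not used for any comparison. The focus ratio, a fraction deposited by the authors for each peak, is given for the untreated peak.

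Lists were compared by overlap of at least 1 bp. Shares have Wilson 95% intervals. Chance overlap was taken from 100 random placements of the 12 h peaks on their own chromosomes, drawn between the first and the last annotated gene. Since both treated lists share a control, 100 pairs of unchanged libraries were also drawn from the untreated tags at the 6085 listed sites, a draw whose outcome the caller's minimums fix in advance. At sites in both lists, the ratio of the normalised tag counts was given on the log2 scale, with an exact binomial (Clopper-Pearson) 95% interval from the tags. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules. They compare the libraries, not the conditions. No test across conditions and no replicate check was possible with 1 library per condition.

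Genes were taken from a RefSeq table of assembly GRCm38.p6, the assembly of mm10, which gave gene spans; transcription start sites, exons and genome sequence were not used here. Distances that had been planned from start sites were therefore taken from the gene span, and the planned motif counts were not run. A gene was counted as having a peak when a peak centre lay in its span or within 25 kb of it. For 12 gene lists of 210 members in all, each of which matched the table, the number of members with a peak was set against 10000 random lists of the same size of protein-coding genes, matched on local gene density in 5 strata. The resulting percentile describes these libraries and is not a p-value. A few genes are members of more than 1 list, and neighbouring genes such as Mt1 and Mt2 can count the same peak.

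The genes and sites named are the 10 highest scoring peaks of the 1 h and of the 12 h list, the 5 highest scoring peaks of each list without a partner in the other, each peak of the untreated list, up to 4 members per gene list by the score of their strongest 1 h peak, the members with a peak at 12 h and none at 1 h, and the values of Per1, Fkbp5, Tsc22d3, Sgk1, Dusp1 and Klf9. Peaks named by rank carry the nearest protein-coding gene. For a member of a gene list, the peak is the highest scoring within 25 kb, and for 21 of the 73 members with a peak another protein-coding gene lay nearer to it. A few items that this rule selects are not reported here. The groups, gene lists, naming rule, planned comparisons and most alternatives were chosen before the data were examined. Several tests of explanations in the closing section were not, and are named there. The comparison of tags at shared sites, further sites named at Zbtb16, members named for having no peak, and the ranking of sites by change were chosen after the values were seen. Alternatives covered the score threshold, the definition of overlap, list length, the distance to genes and the scaling of tags.

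The libraries held 79203826 tags (untreated), 90556119 (1 h) and 97749688 (12 h). The caller's 3 minimums are the tag threshold, which acts on the score (the lowest score was 75 in both treated lists), and the fold over the control and over the local region. The lowest normalised tag counts listed were 7.51 at 1 h and 6.96 at 12 h. An unlisted site has no value, and no fold was computed for it. The overlap, gene assignment and tag ratio steps were tested on simulated data. Of 1500 simulated copies of 1 h peaks, 1500 were recovered as shared and 0 of 500 placed elsewhere were called shared; of 200 sites lowered 4-fold among 5638, 200 were recovered; and 200 of 200 genes given a peak among 21631 were found. The copies were moved by less than a peak width, the peaks elsewhere lay past any chromosome end, and the gene peaks lay at gene midpoints. The overlap and gene outcomes were therefore fixed in advance and check only that the code runs as written. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.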

Results

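GR ChIP-seq peak lists were compared between untreated 33AP1C9 cells and cells that had received 600 nM corticosterone for 1 h or 12 h, with 1 library per condition. The libraries were of similar depth, with 79203826, 90556119 and 97749688 tags. The question addressed was how corticosterone changes where GR binds. Positions are in mm10, and tags are normalised to a library of 10000000 tags unless called raw.

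In untreated cells 1 peak was listed, and it lay 148 bp from the span of Pgk1, a glycolytic enzyme gene (chromosome X, 106186881 to 106187023). It held 317 raw tags, or 40.0 normalised tags, at a fold of 44.2 over the input control. Neither treated list had a peak there, but with the untreated library as their control a treated library would have needed 240.1 tags in that window to list one. After 1 h of corticosterone 5638 peaks were listed, covering 1590 kb and holding 1.68% of the library's tags. After 12 h 2883 peaks were listed, covering 871 kb and holding 0.811% of the tags. The median peak held 18.3 tags at 1 h and 18 at 12 h, and the median fold over the untreated library was 14.2 and 12.5.

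The untreated library served as the background at the treated sites. At the 1 h sites it held a mean of 11.4 raw tags per window, against 10.8 expected from the caller's average tags per base. At the 12 h sites the values were 12.3 against 11.6. That average is given in the file headers and rests on the genome size the caller assumed. At the highest scoring 10% of sites the ratios of mean to expectation were 1.24 at 1 h and 1.25 at 12 h. The median fold of treated over untreated there was 62.7 and 53.4. In the lowest scoring 10% of 1 h sites the mean was 7.53 raw tags. Sites were listed only at a fold of at least 6 over this library, so the means are partly set by that selection. They do not show that the sites lacked signal before hormone. Of the candidate peaks, the caller removed 27.2% at 1 h and 42.7% at 12 h for too low a fold over the control.

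The highest scoring peak of both treated lists lay 86.0 kb from Ptpn1, a protein tyrosine phosphatase gene (chromosome 2, 167844622 to 167844904), with 433 tags at 1 h and 443 at 12 h. Sites inside Pdlim5 (chromosome 3, 142372498 to 142372780), inside Klf13, 51.4 kb from Cdkn2aipnl and 86.1 kb from N6amt1 were also among the 10 highest scoring peaks at both times. In all, 5 sites were common to the leading 10. Zbtb16, a zinc finger transcription factor gene induced by glucocorticoids, held the second peak of the 12 h list inside its span (chromosome 9, 48723613 to 48723915). This peak held 421 tags, against 250.2 in the overlapping 1 h peak (48723688 to 48723970). The untreated library held 6 raw tags in the 12 h window and 3 in the 1 h window. The fold over it was 555 at 12 h and 661 at 1 h. The log2 ratio of 12 h over 1 h there was 0.75 (95% counting interval 0.68 to 0.82). Fkbp5, an HSP90 co-chaperone gene that restrains GR, held 264 and 284 tags at its main site (chromosome 17, 28420204 to 28420486), a log2 ratio of 0.11 (0.03 to 0.19) that became 0.01 when tags were taken per base of the window.

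Other leading 1 h sites held fewer tags at 12 h. The site 89.2 kb from Tbl1xr1 held 302.0 tags at 1 h and 101 at 12 h (log2 ratio -1.58, -1.69 to -1.48), and the site inside Pde4d, a cAMP phosphodiesterase gene, held 307 and 112 (log2 ratio -1.45, -1.56 to -1.35). Sites inside Tns1, inside Hhat and 55.6 kb from Eif3h were lower in the 12 h library as well, with 342 and 186, 339.6 and 210.1, and 325 and 157 tags. Among the leading 12 h sites, those nearest to 1700056E22Rik and Adra1b held 257 and 261, and 257 and 256 tags, within counting error of each other, and the site nearest to Bpnt2 held 297 and 219. Each of the 10 leading sites of either list had a peak in the other list.

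Most sites listed at 12 h had been listed at 1 h, while the share of 1 h sites listed at 12 h depended on how far above the caller's minimums they stood. Of the 2883 peaks at 12 h, 2436 overlapped a 1 h peak (84.5%, Wilson interval 83.1 to 85.8%), and these made up 43.2% (41.9 to 44.5%) of the 1 h list. The remaining 3202 peaks were in the 1 h list only and 447 in the 12 h list only. Random placements of the 12 h peaks overlapped a median of 4 (range 0 to 10) 1 h peaks. The part of the overlap that comes from the untreated control shared by both lists was not measured. Libraries drawn from the control's tags, a mean of 11.4 per 1 h window, gave 0 shared sites by construction. Such draws stay near the control, while a listed site must reach both the threshold of 75 and the minimum fold over that control. With equal numbers of leading peaks from both lists, the shared proportion was 63.5% in either direction. Of the 1 h peaks at 2 or more times each of the caller's minimums, a limit chosen after the data were seen, 75% were listed at 12 h.

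Sharing followed peak strength. Of the lowest scoring 10% of 1 h peaks 14.4% (11.7 to 17.5%) were listed at 12 h, against 94.3% (92.1 to 96.0%) of the highest scoring 10%. In the 12 h list 64.7% of the lowest and 99.3% of the highest scoring 10% were listed at 1 h. Shared peaks had a median score 2.0 times that of 1 h only peaks (1.92 to 2.09, bootstrap interval), and in the 12 h list the ratio to 12 h only peaks was 1.62 (1.51 to 1.70).

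**Figure D1:**
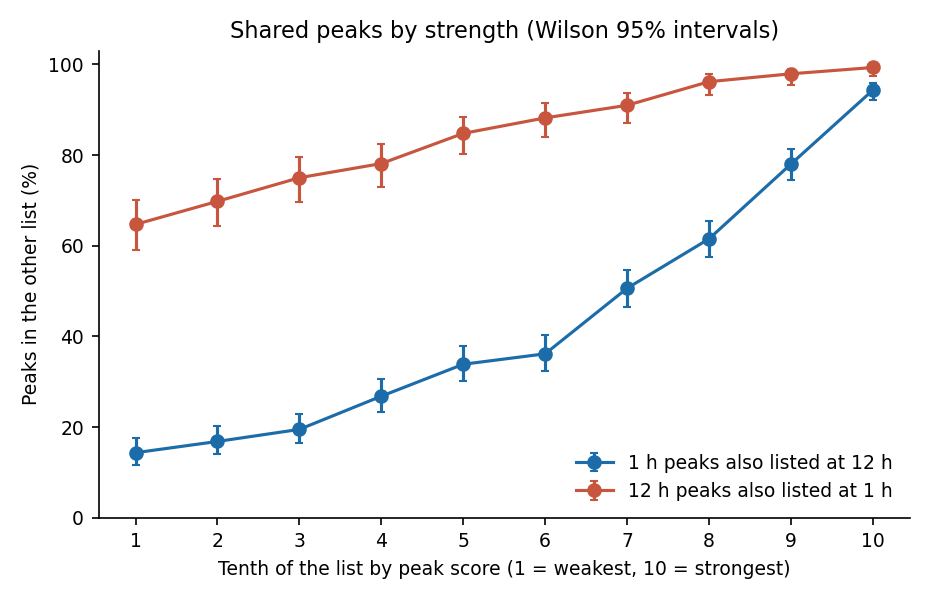
Percentage of peaks of one list that overlap a peak of the other, in 10 equal groups by peak score from weakest (1) to strongest (10); points are shares and bars are Wilson 95% intervals. The 1 h list goes from 14.4% to 94.3% and the 12 h list from 64.7% to 99.3%.

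The strongest sites in the 1 h list alone were 64.2 kb from Zfp36l2 (162 tags), inside Hhat (147), inside Rapgef2 (142), 69.8 kb from Cpe (122) and inside Nek7 (111). To reach the fold over the untreated library at 12 h, 1 of the conditions for being listed, the Rapgef2 site (chromosome 3, 79193156 to 79193438) would have needed 9.09 tags and the Nek7 site (chromosome 1, 138571482 to 138571764) 7.58. The strongest in the 12 h list alone were next to St6galnac1 (68.7 tags), inside Tns1 (64.2), inside Oxr1 (53.1), inside Dchs2 (44.5) and 342 kb from Adamts5 (44.5). The St6galnac1 site held 62 raw tags in the untreated library, so that up to 47.0 tags at 1 h would have left it unlisted. For the Oxr1 and Dchs2 sites the corresponding values were 28.0 and 23.5 tags. An unlisted site can also have failed the caller's minimum score or fold over the local region, for which no value is given at that time. Where listed, the local fold was 6.69 at the Tns1 and 7.44 at the Oxr1 site, against a minimum of 6. It was 10.01 at the Zfp36l2 and 9.42 at the Hhat site, and 13.9 to 49.53 at the other sites named here. Shared peaks of 341.6, 113.1, 255.6 and 339.6 tags at 1 h lay near the Tns1, Oxr1, Zfp36l2 and Hhat sites. A single listing there need not be a gain or loss of binding.

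At the 2436 shared sites the 12 h library held fewer tags than the 1 h library at 1881 and more at 555. The median log2 ratio was -0.49 (-0.53 to -0.46, bootstrap over sites), or 0.710-fold. Sites lost from the 12 h list have no ratio, and the weakest 1 h sites were lost most often, so these values hold for sites that stayed listed. Sites at least 2-fold lower numbered 596, and sites at least 2-fold higher 35. Among the 532 shared sites in the highest scoring 10% at 1 h the median was -0.85, with 479 lower and 53 higher. These sites were chosen for a high value at 1 h, by which the ratio divides, and that choice alone lowers it. The 2 medians therefore do not show that the strongest sites lost most. Summed over shared sites, 1.11% of the 1 h tags and 0.748% of the 12 h tags fell in peaks, with a mean of 45.7 and 30.7 per site over 687 and 736 kb.

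**Figure D2:**
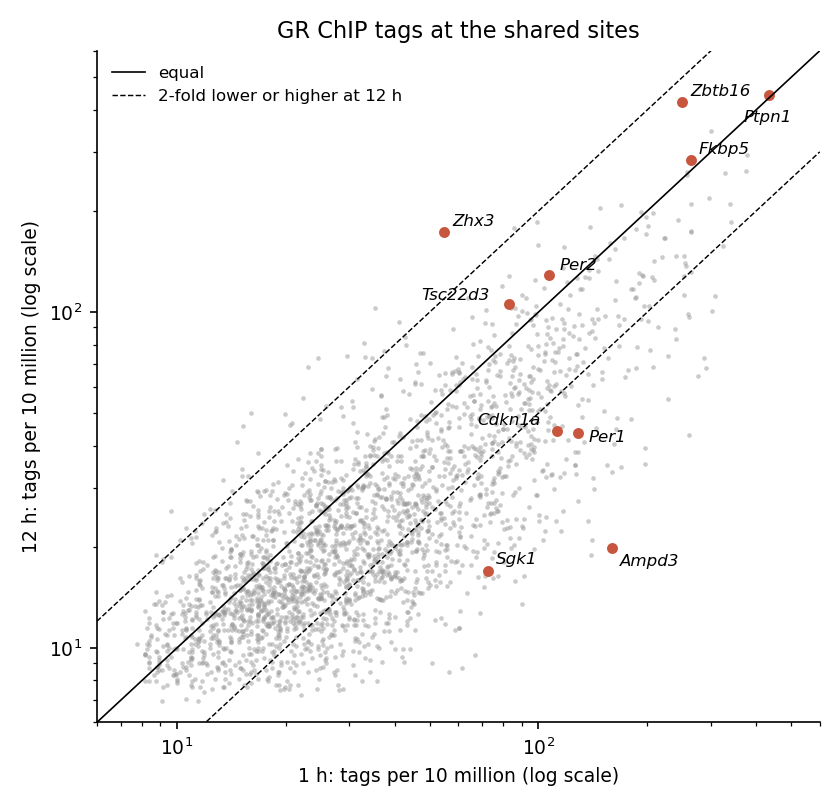
Tags, normalised to 10000000 per library, at the 2436 shared sites, 1 h on the horizontal and 12 h on the vertical axis, both logarithmic; grey points are sites, red points the named ones, and lines mark equality and a 2-fold difference. Most points lie under equality (1881 of 2436), with Zbtb16 and Zhx3 above it and Sgk1 and the site 51.9 kb from Ampd3 below.

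Established glucocorticoid target genes carried GR peaks more often than random lists of genes. Of 28 core target genes 23 had a peak within 25 kb at 1 h and 18 at 12 h, against a median of 5 (95% range 1 to 9) and 3 (0 to 6) in random lists, the 100th percentile at both times. Peaks were listed at both times for 18 members and at 1 h alone for 5, which were Nfkbia, Lcn2, Angptl4, Suox and Rgs2. Cebpd, Cebpb, Cdkn1c, Tiparp and Bcl6 had none at either time. Across 21631 protein-coding genes, 17.1% had a peak at 1 h and 9.33% at 12 h.

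Sites within 25 kb of the core genes went different ways between the libraries. Per1, a repressor of the circadian clock, had a pair of sites inside its span: the one at 69099286 to 69099568 on chromosome 11 held 128.5 tags at 1 h and 43.5 at 12 h (log2 ratio -1.56, -1.73 to -1.40), and the one at 69096933 to 69097215 held 106 and 90.3 (-0.23, -0.37 to -0.10). Sgk1, a serum- and glucocorticoid-regulated kinase gene, held 72.3 and 17.0 tags at the site 5.12 kb outside its span (-2.09, -2.35 to -1.84) and 46.9 and 34.2 at the one inside. Tsc22d3, which encodes the anti-inflammatory protein GILZ, had 6 sites at 1 h and 5 at 12 h; the one with most tags within 25 kb of the gene (chromosome X, 140529198 to 140529480) held 82.9 and 106 tags (0.35, 0.21 to 0.48), and its site at 140520202 held 55.0 and 34.0. Dusp1, a MAP kinase phosphatase gene, held 45.7 and 23.5 at its main site (-0.96, -1.20 to -0.72), and Klf9, a Krüppel-like factor gene, 37.5 and 38.1 (0.02, -0.20 to 0.24). Single sites of Fkbp5 (43.4 tags), Klf9 (26.0), Dusp1 (10.9) and Tsc22d3 (10.0) were in the 1 h list only. Their folds over the local region at 1 h were 21.7, 8.34, 6.54 and 9.68, against a minimum of 6. Absence from the 12 h list need not be a loss of binding. In the untreated list none of these genes had a peak, and the untreated library held between 4 and 19 raw tags at their sites. Of the other leading core members, Ampd3 held 196 and 104 tags at its strongest 1 h site within 25 kb.

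**Figure D3:**
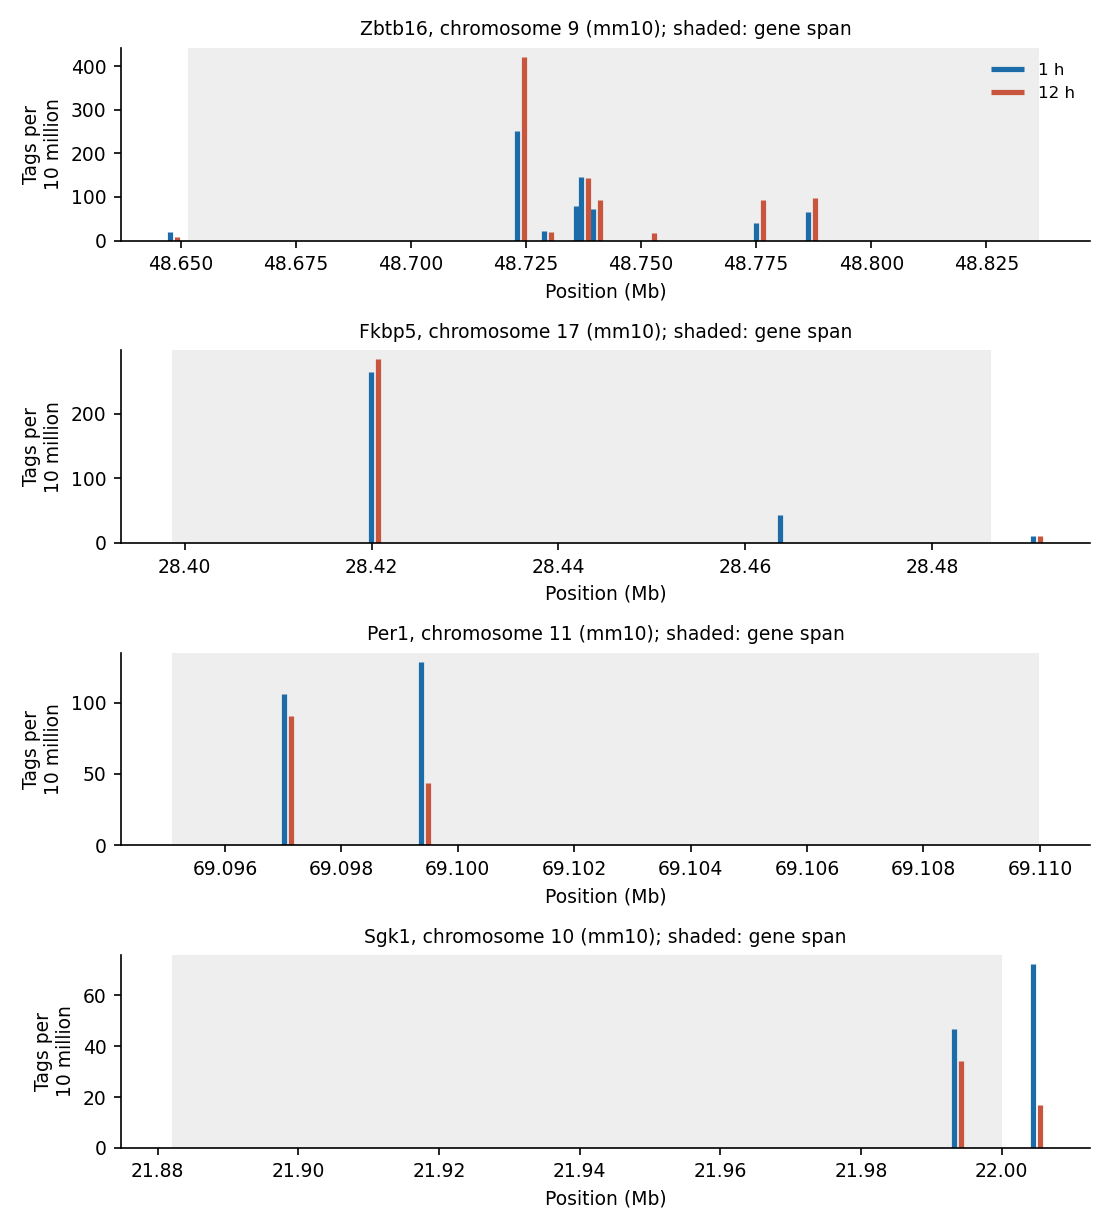
GR peaks at Zbtb16, Fkbp5, Per1 and Sgk1, with position in Mb (mm10) on the horizontal axis and normalised tags on the vertical axis; blue lines are 1 h and red lines 12 h peaks, drawn slightly to either side of the peak centre, and the gene span is shaded. The main Zbtb16 site goes from 250.2 to 421 tags, and the Sgk1 site outside the gene from 72.3 to 17.0.

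The circadian clock list had a peak at 8 of 19 members at 1 h and 6 at 12 h (percentiles 99.5 and 99.7), Per1 being shared with the core list. Within 100 kb the 12 h count was 8, at the upper end of the random range of 1 to 8 (percentile 97.3). Tef, a clock output factor gene, held 195 and 128 tags at its strongest site within 25 kb, which is nearer to Tob2 (log2 ratio -0.61, -0.72 to -0.50), Per2 held 107 and 129 (0.28, 0.15 to 0.40), and Ciart held 60.4 and 16.8 (-1.85, -2.11 to -1.59). The inflammatory list had 6 of 21 members at both times (percentiles 90.2 and 99.4), with 71.8 tags at 12 h against 75 at 1 h near the chemokine gene Cxcl5; Cxcl1 and Cxcl2 counted the same peak, and Tnfaip3 held 18.4 and 14.5. Within 10 kb of the gene, 3 members had a peak at 12 h (percentile 91.2), and within 100 kb 8 did (94.2).

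Lists chosen as contrasts did not all stay low. Housekeeping genes had a peak at 6 of 15 members at 1 h (percentile 99.0) and 2 at 12 h (76.7); Hprt, a purine salvage enzyme gene, held 126.7 tags at 1 h and 32.9 at 12 h (-1.94, -2.13 to -1.76) at a site 16.9 kb away and nearer to Phf6, Tbp held 29.5 and 11.7, and Actb 20.9 at 1 h alone. Within 10 kb, 2 housekeeping members had a 1 h peak (percentile 69.5), and within 100 kb 9 did (96.6). Neuronal markers had 5 and 4 of 15 (percentiles 89.6 and 95.5), with 99.1 and 28.6 tags at the strongest 1 h site of Gad2 and 59.0 and 58.3 at Map2. Another Gad2 site was the strongest there at 12 h, with 45.6 tags. Within 10 kb the 12 h percentile of the neuronal list was 98.4. Immune markers had 1 and 0 of 15 (17.1 and 12.9), the 1 being Itgam with 17.8 tags; within 100 kb the 12 h count of 0 lay under the random range of 1 to 7. Liver target genes had 2 and 1 of 15 (33.8 and 36.8), with Cyp2b10 at 28.5 and 52.1 tags (0.87, 0.65 to 1.09) and G6pc at 9.72 at 1 h alone.

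The remaining lists lay within the range of random lists at 25 kb. AP-1 factor genes had 3 and 2 of 11 members (percentiles 80.2 and 82.4), with Junb at 32.5 and 7.98 tags, Jund at 13.5 and 12.7 and Maff at 31.6 at 1 h alone. The Junb and Jund sites lay 10.1 and 10.0 kb away, nearer to Rnaseh2a and Iqcn. Within 100 kb the list had 8 and 6 members, above the random ranges of 1 to 7 and 0 to 5 (percentiles 98.8 and 98.9). Growth signal feedback genes had 5 and 4 of 16 (83.4 and 92.6), with Rasa3 at 67.9 and 74.2 tags and Errfi1 at 29.2 and 14.6; Spred2 had a peak at 12 h alone (10.8 tags, 19.4 kb away). Steroid pathway genes had 5 and 3 of 18 (80.3 and 77.4), with Ncoa2 and Hsp90ab1 at 18.3 tags each at 1 h alone. The Hsp90ab1 site lay 23.5 kb away and nearer to Slc29a1. Hsd11b2, which inactivates corticosterone, had 16.5 tags at 12 h alone. That site lay 22.8 kb away and nearer to Atp6v0d1, at a fold of 7.67 over the untreated library, where the minimum was 6. Mammary epithelial genes had 5 and 3 of 21 (77.3 and 76.2), with Krt7 at 110.5 and 66.2 tags and Krt8 and Krt18 sharing a site of 28.9 and 27.5. Basal and mesenchymal genes had 6 and 2 of 16 (93.6 and 56.7), with Col3a1, a collagen gene, at 238 and 89.0 tags (-1.42, -1.54 to -1.31), Trp63 at 56.0 and 39.9, Sparc at 21.3 and Zeb2 at 16.8 at 1 h alone; within 10 kb the 1 h percentile was 98.3. Over the 24 comparisons of a list at a time, 0.6 would be expected above the 95% range of random lists by chance.

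**Figure D4:**
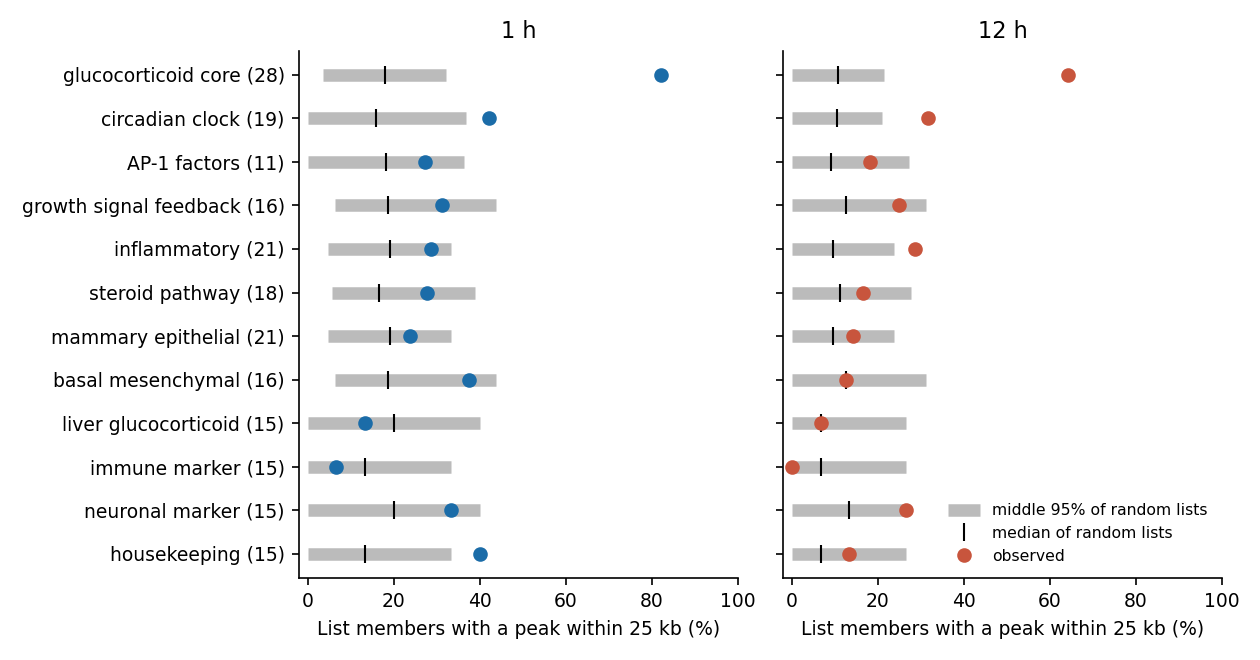
Percentage of the members of 12 gene lists (number of members in brackets) with a peak within 25 kb at 1 h and 12 h; coloured points are observed values, grey bars the middle 95% and black ticks the median of 10000 random lists. The glucocorticoid core list lies at 82.1% and 64.3%.

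The share of peaks inside protein-coding genes lay just above the range of random placements at 1 h and within it at 12 h. At 1 h 42.9% (41.6 to 44.2%) were inside a gene, against a median of 40.3% (38.5 to 42.0%) at random, and at 12 h 40.5% (38.7 to 42.3%) against 40.2% (38.0 to 42.2%). Positions within 1 kb of a gene end held 3.42% of 1 h and 2.71% of 12 h peaks, against 3.09% at random for both. Peaks outside genes lay a median of 39.5 kb at 1 h and 42.2 kb at 12 h from the nearest one.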

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

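Of the tests in this part, the one on copies of the Pgk1 region was chosen after the result was seen. In the untreated library, which the comparisons use only as background, 1 peak stood out above its input control, near Pgk1, with a fold of 44.2 over the control. The control held 7.20 tags in the window after scaling, 1.32 times the caller's genome-wide expectation. A listed peak had to stand at least 6-fold over this control, so a high control count was largely excluded beforehand. The value therefore cannot decide whether extra copies of the region in the genome of the cells were the source. A focus ratio of 0.632 compares with a median of 0.841 in the 1 h list. The peak may reflect material specific to that immunoprecipitation, and binding of the receptor or another protein without added hormone remains untested with 1 library. The treated lists cannot show whether the signal recurs, since this library was their control.

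On the unplaced scaffold Un_GL456360, outside the chromosomes used for the gene comparisons, the 1 h list held 1 peak of 13.0 normalised tags, above the 5 raw tags of the untreated library, at a fold of 20.6.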

How the results depend on the processing

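Alternatives that scaled tags differently, matched random lists on gene length, paired shared sites by centres within 100 bp for the tag ratio, or limited 1 h peaks to those at 2 or more times each minimum were chosen after seeing the data; the others had been planned. No paired analysis was possible because the groups share only 1 replicate number. Of the 1784 shared sites whose counting interval excluded 0, 0 changed direction with untreated tags subtracted. A similar small count was taken from both libraries at each site, so this outcome was largely fixed in advance. Taking tags per base lowers each ratio by the same amount, from the fixed window widths. The leading sites nearest to Ptpn1 and 1700056E22Rik, whose intervals include 0, went from 0.03 and 0.02 to -0.07 and -0.08 per base of window. Keeping only peaks scoring at least 2 times the lowest of their list left 3285 at 1 h and 1802 at 12 h by construction, and 46.5% of the 1 h peaks were then found at 12 h. With centres within 100 bp the shares were 81.1% of the 12 h and 41.5% of the 1 h list. With equal numbers of leading peaks both were 63.5%, and of 1 h peaks at 2 or more times each minimum 75% were found at 12 h; the low share of the full 1 h list thus rests in part on peaks near the minimums. Within 5 kb of a gene end lay 14.4% of 1 h and 12.8% of 12 h peaks, a wider window by construction. The median log2 tag ratio was -0.59 per base of window, where the 12 h windows are wider, and -0.54 with untreated tags subtracted. A ratio of scores across the lists was also tried and set aside, the score being a value for use within a list. The core gene counts of 23 and 18 stayed within 1.5 times under each alternative run. For the other 11 lists 41 of 66 alternatives did so, and 17 of 30 alternatives at named sites stayed within counting error. Random lists matched also on gene length moved the steroid percentile at 1 h from 80.3 to 57.9, the neuronal ones from 89.6 and 95.5 to 75.4 and 89.4, the AP-1 ones from 80.2 and 82.4 to 93.7 and 93.4, and the inflammatory one at 1 h from 90.2 to 96.9. The growth signal feedback percentiles went from 83.4 and 92.6 to 94.2 and 97.1, still within the random range. The lists above their random range were the same, with percentiles of 99.2 and 99.5 for the clock list, 99.8 for the inflammatory list at 12 h and 99.4 for housekeeping genes at 1 h. The planned counts of the GR response element and other motifs were not run, a genome sequence not being used here, and settings from start sites were run from gene spans. A stricter score for the untreated list has no meaning with 1 peak. Depth limits sites near the lowest score of 75, where a peak is listed or not by few tags.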

Other observations

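Tests on counting noise, on sites and peaks at the core genes and on which 1 h peaks were lost were chosen after the results were seen, as were the ranking of sites by change and the loci named here; the other tests had been set out before their results were seen. Among 1261 shared sites with at least 30 normalised tags in either library, 479 were at least 2-fold lower and 25 at least 2-fold higher at 12 h. The site lowest at 12 h against 1 h lay 51.9 kb from Ampd3, an AMP deaminase gene, with 159 tags at 1 h and 19.9 at 12 h (7.99-fold), whereas the site inside Ampd3 held 196 and 104. The next, at 28512846 on chromosome 17, lay 17.9 kb from Armc12 and past the end of the Fkbp5 span at 28486149, with 140 and 18.9 tags (7.38-fold), while the main Fkbp5 site held 264 and 284. Sites inside Clvs1 (140.6 and 21.0 tags) and 65.7 kb from 4930432M17Rik (260.4 and 43.0) followed the same direction. In the opposite direction, a site inside Zhx3, a zinc finger and homeobox gene, held 54.8 tags at 1 h and 173 at 12 h (log2 ratio 1.66, 1.52 to 1.81). The site 28.7 kb from Irf2 held 16.0 and 50.2, and the site 35.0 kb from Pax3 held 24.5 and 73.2.

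Some genes gathered many peaks, over spans of very different length. Csmd3 (1211921 bp) and Tns1 (214317 bp) each had 11 peaks at 1 h and 8 at 12 h, Zbtb16 (184429 bp) had 8 and 8, and Sox5 (953863 bp) 8 and 5. Gse1 (352883 bp) and Mical2 (129370 bp) each had 7 at 1 h and 1 at 12 h. Within Zbtb16 the site at 48775678 on chromosome 9 held 41.0 tags at 1 h and 93.5 at 12 h (log2 ratio 1.19, 1.01 to 1.37), the site at 48786814 held 65.3 and 96.7, and the site at 48737496 held 145 and 144. The site at 48729523 held 21.6 and 18.5, and one at 48648267, 3.39 kb outside the span, 18.8 and 7.77. Inside the span, a site at 48736430 was listed at 1 h alone with 79.0 tags, and one at 48751894 at 12 h alone with 17.6. The fold over the local region at 48736430 was 8.27 at 1 h, against a minimum of 6, and the shared site at 48737496 lay close to it. Absence of the site at 48736430 from the 12 h list need not be a loss of binding.

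The first pattern weighed is the shorter list at 12 h. Scaling each 1 h peak by 1 common ratio, the 0.555-fold median of the highest scoring 10% of shared sites, with Poisson counting and the caller's 3 minimums kept a median of 2481 peaks (2451 to 2516 over 100 draws), against 2436 observed. That total depends on the ratio, which came from sites chosen for a high 1 h score and still listed at 12 h. Over all shared sites the median was 0.710-fold. The total also adds up opposite differences by strength: of the lowest scoring 10% 81 peaks were listed at 12 h against 0 to 2 in the draws, and of the eighth of 10 score groups 347 against 443 to 463. Of 1744 peaks kept in each draw, 359 were not listed at 12 h, and 339 of the 1999 never kept were listed, but the draws hold counting noise alone, and other variation between the libraries would give such losses and gains too, so a uniformly lower enrichment in the 12 h library is left open, as neither shown by the total nor excluded. Among the 447 peaks listed at 12 h alone, 12 stood at 2 or more times each minimum (score and both folds), past the bound of 10 set beforehand, but a Poisson interval of 6.2 to 21.0, added after the count was seen, includes that bound, so these counts are too few to decide. The peak inside H6pd, among these 12, lay closer to a 1 h peak than the 564 bp the caller required between 1 h peaks. It could not have been listed beside that peak at 1 h. For the common part of the loss, a lower immunoprecipitation yield and less binding after 12 h of hormone both stay open, since each condition has 1 library.

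The second pattern is that the 12 h to 1 h tag ratio differs between shared sites. The spread of the log2 ratios was 4.93 times that from counting, 0.71 against 0.14, which argues against counting noise around a single ratio. Chromosome explained 1.15% of the variance, which argues against whole-chromosome copy number differences between the cultures as the main source of this spread. Smaller differences and copy number changes of chromosome segments were not tested. Variation between libraries beyond counting stays open and was not tested, as does a site-specific response to the time in hormone.

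As a hypothesis, neighbouring sites may share their change. Over 437 pairs of neighbouring shared sites 2 to 50 kb apart, the log2 ratios, adjusted for level, correlated at r = 0.211 across sites, above the range of 1000 shuffles (-0.175 to 0.137); sites are not independent replicates. Without the pairs at Zbtb16 the value was 0.193 over 432 pairs, and over 1044 pairs of next neighbours 100 to 1000 kb apart it was 0.0804, the last 2 values being added after the first was seen. A tendency of local chromatin to set the change is a candidate explanation, and local differences in yield were not excluded. A second hypothesis, that sites at the core genes kept more than other sites of like strength, could not be decided. Their 34 shared sites had a median log2 ratio of -0.57, at percentile 85.0 of matched random sets (95% range -1.0 to -0.46), but shared sites leave out those lost at 12 h, so that value decides nothing. Over the 52 peaks listed there at 1 h, lost ones included, 34 were listed at 12 h, against a median of 33 (28 to 39) in random sets matched on score, percentile 60.2.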
